A study of Homo sapiens with 18 samples.

How the data were processed

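Ribosome-protected fragments (RPF, the stretches of mRNA shielded by a ribosome), total RNA and tRNA were sequenced from PATU-8902 cells, an established human pancreatic ductal adenocarcinoma line. Per the labels, 25000000 cells were seeded on a 15 cm plate and then held for 24 h in medium with 2.78 mM glucose, 4 mM glutamine, 1 mM pyruvate and 10% dialysed serum, either with 400 µM serine and 400 µM glycine or without both amino acids. Groups and replicate numbers were taken from the labels, which gave 3 libraries per kind and medium and 18 in all. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

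Per the submitters' processing notes, cutadapt was used and reads were placed on hg38 for total RNA and RPF and on hg19 for tRNA. The aligner, the transcript set, the assignment of footprints to positions and the treatment of reads with several matches are not given in the sources used here. Genes with pseudogenes or near-identical copies, above all ribosomal protein and histone genes, are therefore uncertain. The deposited gene values were expected counts per coding sequence, with a decimal part in some entries, for 18660 transcripts with 18645 symbols. They were rounded to whole numbers. The deposited lengths were coding lengths, since 99.995% were multiples of 3. The deposited codon tables held a read density signal at each offset up to 150 nt on either side of the 61 sense codons, relative to a mean that no header explains. No offset 0 was listed, and neither the decoding site nor the orientation of the offsets was marked. Per the file headers, the tRNA charging table held counts of reads that end in CCA (charged, protected from oxidation) and in CC (uncharged), with the charged fraction made from them, for 237 tRNA isodecoders (tRNAs with 1 anticodon but different bodies). A further deposited table gave the fraction of reads per anticodon in 79 classes, with names limited to 6 characters. Of the symbols in the count tables, 17580 were current and 1011 were synonyms in the RefSeq table of GRCh38.p14, the assembly of all coordinates given, and 54 had no match.

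Summed coding counts ranged from 539835 to 1011635 in total RNA and from 2585178 to 6288859 in RPF, and tRNA reads from 4963888 to 8839195. Floors are 3 counts over a group and cover counting error only, as reads without molecular identifiers are not independent molecules. No pair of libraries in a group was identical.

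Total RNA and RPF were each tested over their own 6 libraries with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), after filterByExpr and TMM scaling. Translational efficiency, the change in RPF beyond that in total RNA, was tested as the interaction of library kind and medium in 1 edgeR model over all 12 libraries. All p-values are two-sided, all adjusted values follow Benjamini and Hochberg, and the threshold was 0.05. Changes are given as log2 without over with serine and glycine, with the standard error (SE). CPM, the usual counts scaled to a common library size, use the TMM scale. The 26 gene lists were fixed before the data were examined and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of each test, and again with an estimated correlation. Genes were named by a rule also fixed then. It took the 8 largest rises and 8 largest falls among called genes with mean log2 CPM of at least 3 and no overlap between groups, leaving out pseudogenes and readthrough genes, up to 2 members of each list per direction, and, whether or not they passed, genes that included PHGDH, PSAT1, PSPH, SHMT1, SHMT2, ASNS, ATF4, SARS and GARS. Of codons it took those for serine and glycine and the 10 largest other changes, and of tRNAs those for serine and glycine. A few further genes belong to 3 lists chosen after their values were seen and appear only among the other observations.

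Codon density was tested with limma over the 61 codons, on log2 of the density at the 2 offsets next to the codon over that beyond 100 nt on both sides. The plan had named offset 0, which the tables lack. Density at offsets 21 to 80 over that at -80 to -21 was examined in addition after the profiles had been seen. Charging was tested with limma on the raw fraction, because it reached both ends of its range, and also as fractions summed by anticodon, a choice made after seeing the table. Abundance was tested with limma on log2 of the share plus 1e-06. Software tests on simulated data used the means, dispersions and library sizes of the real data. The edgeR step recovered 50% of 4-fold changes in total RNA (8481 genes), 87.9% in RPF (10212 genes) and 60.6% in translational efficiency (10211 genes), and 19.4%, 52.2% and 16.4% of 2-fold changes. False calls were 2%, 6% and 5.6% of calls. All 10 altered codons were recovered with 0 false calls, and all 18 altered isodecoders with 3 false calls.

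Alternatives tried were other scaling, filters and thresholds, DESeq2 1.42.0, a fit over all 12 libraries, thinned RPF counts, replicate number as a block, other offsets and scales, and leaving out each library in turn. Mitochondrially encoded proteins were not analysed here. The relation of codon content to the change of each gene needs coding sequences and was not analysed here.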

Results

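The series asked how pancreatic cancer cells translate mRNA when serine and its product glycine are missing. PATU-8902 cells with and without the 2 amino acids were compared in total RNA, ribosome footprints and tRNA, with 3 libraries per group. Total RNA libraries held 972434, 855242 and 539835 coding counts with serine and glycine and 766023, 928478 and 1011635 without. RPF libraries held 2585178, 5789656 and 6288859 with and 4601308, 3318096 and 3356095 without. tRNA libraries held 6172976, 8721336 and 8839195 reads with and 4963888, 5276550 and 7586338 without. The first enzymes of serine synthesis, PHGDH (chromosome 1, 119711934 to 119744215) and PSAT1 (chromosome 9, 78297125 to 78330093), had 0 counts in all 12 total RNA and RPF libraries. With a floor of 3 counts over a group this allows up to 1.27 CPM with and 1.11 CPM without serine and glycine in total RNA, and 0.205 and 0.266 CPM in RPF. Whether the cells or the way reads were assigned to transcripts accounts for these zeros was not tested, and 5643 of 18660 transcripts were at 0 in all 12 libraries. PSPH, the last enzyme of the pathway, was present at 59.7 ± 9.63 CPM with and 57.3 ± 8.35 CPM without the amino acids in total RNA (SD, n = 3 each; log2 change -0.06, SE 0.36, adjusted p = 0.955).

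The charging of tRNAs was compared to ask which tRNAs lost their amino acid. Every serine anticodon class, cytosolic and mitochondrial, carried less amino acid without serine and glycine, whereas the glycine classes stayed near their former level. tRNA-Ser(AGA) fell from 59.2% ± 0.871 charged to 16.4% ± 1.36 (SD, n = 3 each; limma adjusted p = 1.69e-07). tRNA-Ser(TGA) fell from 58.6% ± 1.88 to 17.1% ± 1.39 and tRNA-Ser(GCT) from 51.4% ± 1.70 to 19.1% ± 0.359 (adjusted p = 4.51e-07 for both). tRNA-Ser(CGA) had the highest charge of the cytosolic serine classes without the amino acids, going from 54.6% ± 1.07 to 32.6% ± 1.92 (adjusted p = 9.3e-06). The mitochondrial serine tRNAs with anticodons TGA and GCT fell from 88.2% ± 0.268 to 54.1% ± 3.20 and from 55.6% ± 1.74 to 28.9% ± 3.54 (adjusted p = 6.1e-06 and 5.87e-05). For glycine, the GCC class stood at 91.7% ± 1.10 with and 89.2% ± 1.26 without the amino acids (adjusted p = 0.181), TCC at 93.1% ± 0.751 and 91.1% ± 1.74 (0.327), CCC at 92.2% ± 0.915 and 91.5% ± 0.725 (0.613), and the mitochondrial TCC class at 89.9% ± 1.07 and 90.4% ± 0.368 (0.692). The GCC class passed the threshold on the logit scale (adjusted p = 0.0464) and with edgeR on the read counts (adjusted p = 0.000187).

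**Figure D1:**
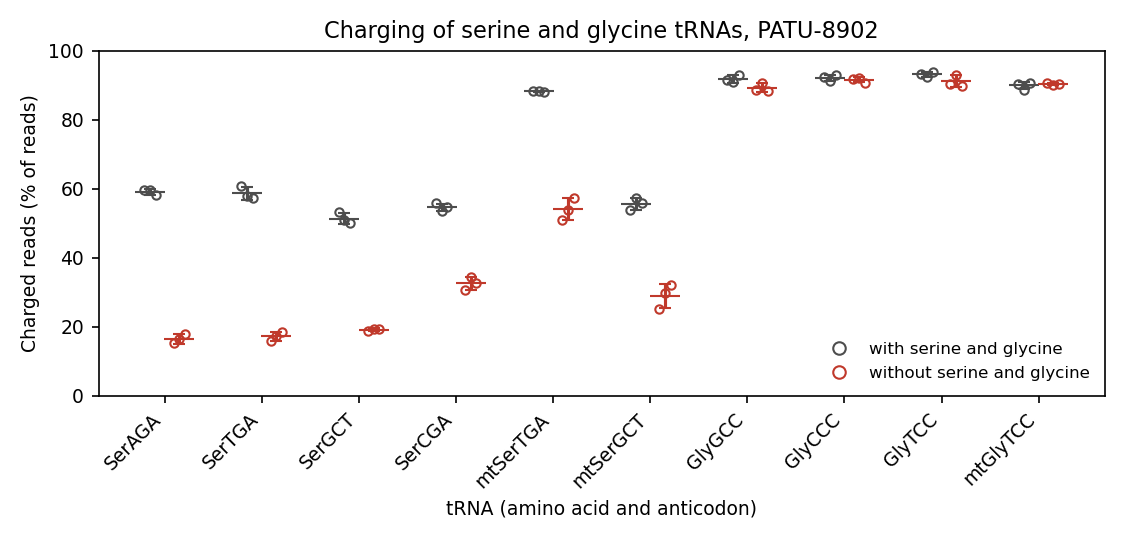
Charged reads as a percentage of all reads for each serine and glycine anticodon class, with each of the 3 libraries per medium as a circle and the mean and SD as a dash and bar. The cytosolic serine classes lie between 50 and 60.8% with serine and glycine and between 15.1 and 34.5% without, while the glycine classes lie between 88.3 and 93.7% in both media.

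Of all isodecoders listed, 1 could not be tested, and 26 changed, 23 of them downward. They included 16 of 20 cytosolic and 2 of 2 mitochondrial serine isodecoders, all lower, and 1 of 8 cytosolic glycine isodecoders, which was higher but rested on 12 to 38 reads per library. The 7 with at least 100 reads had a median change of -2.08 points, and none of them was called. The 41 cytosolic anticodon classes other than serine, glycine included, had a median charge of 90.2% with and 89.4% without serine and glycine. Outside serine, 3 mitochondrial classes passed the threshold. tRNA-His(GTG) rose from 49.4% ± 1.39 to 60.5% ± 3.48 (SD, n = 3 each; limma adjusted p = 0.00667). tRNA-Asn(GTT) went from 88.1% ± 0.542 to 90.9% ± 0.621 and tRNA-Thr(TGT) from 50.5% ± 2.27 to 42.9% ± 2.46 (adjusted p = 0.0219 for both). The asparagine call was lost without plus replicate 1, 2 or 3 or minus replicate 3 (limma adjusted p 0.0545, 0.0908, 0.0635 and 0.0972), and the threonine call without plus replicate 2 or 3 (0.0739 and 0.0574). Of 67 classes, 9 were called with all libraries and 16 without minus replicate 2.

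In tRNA abundance, measured as the share of reads per anticodon, 2 of 79 classes changed. tRNA-Pro(TGG) rose from 1.14% ± 0.427 to 6.79% ± 2.71 of reads (SD, n = 3 each; log2 change 2.57, SE 0.39, limma adjusted p = 0.0116), and a class named as undetermined rose from 0.000509% ± 0.000178 to 0.00235% ± 0.00065 (log2 change 2.02, SE 0.29, adjusted p = 0.0116). tRNA-Ser(AGA) was at 0.458% ± 0.491 and 0.0586% ± 0.0122 (log2 change -2.42, SE 0.71, adjusted p = 0.1), with 1.02% in plus replicate 1 against 0.221% and 0.13% in the others. tRNA-Ser(TGA) was at 1.87% ± 0.873 and 3.40% ± 0.802 (adjusted p = 0.243), Ser(GCT) at 3.37% ± 0.259 and 3.91% ± 1.03 (0.688) and Ser(CGA) at 0.375% ± 0.0329 and 0.355% ± 0.0708 (0.817). The mitochondrial serine classes were at 1.32% ± 0.265 and 0.932% ± 0.144 (adjusted p = 0.243) and at 0.0245% ± 0.0161 and 0.021% ± 0.00291 (0.961). The glycine classes GCC, CCC and TCC had log2 changes of -0.28, -0.35 and -0.05 (adjusted p 0.473, 0.447 and 0.912). The selenocysteine class with anticodon TCA held 3.38e-05% ± 4.07e-05 and 0.000119% ± 5.57e-05 of reads (adjusted p = 0.234). The number called was 4 without plus replicate 1, 0 without plus replicate 2 (12 at an unadjusted p under 0.05 with limma), 1 without plus replicate 3, 6 without minus replicate 1 and 0 without minus replicate 2 (18 unadjusted). On the untransformed share 4 classes were called, among them 0 of the 2 named first.

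Ribosome density around codons was compared to ask whether footprints gathered at particular codons. At the 2 offsets next to the codon, which need not be where ribosomes decode it, 24 of 61 codons changed in RPF, 6 upward and 18 downward. Of the serine codons, TCA fell by 0.33 on the log2 scale (SE 0.05, n = 3 per group, limma adjusted p = 0.00199) and AGT rose by 0.17 (SE 0.04, adjusted p = 0.0176). TCT, TCC, TCG and AGC had changes of 0.02, 0.00, -0.10 and 0.07 (adjusted p 0.885, 0.986, 0.0701 and 0.236). The glycine codons GGA, GGC, GGG and GGT lay between -0.01 and 0.07 (adjusted p 0.735, 0.929, 0.238 and 0.89). The largest rise was at the lysine codon AAA (0.45, SE 0.09, adjusted p = 0.00527) and the largest fall at the valine codon GTT (-0.35, SE 0.05, adjusted p = 0.00199). Apart from serine codons, the next largest were falls at TAT and TAC for tyrosine (-0.30 and -0.27), TTT for phenylalanine (-0.26), GTC (-0.25), CGA (-0.24) and GCT (-0.24), and rises at GAA (0.26) and AGA (0.24). Without RPF plus replicate 1, the calls at GCT, GAA and AGA were lost (adjusted p 0.0688, 0.0948 and 0.0918), and those at GAA and AGA also without plus replicate 2 (0.0751 and 0.0511), minus replicate 1 (0.0615 and 0.0524) or minus replicate 2 (0.068 and 0.0514). In total RNA, which has no decoding site, limma called 0 codons (2 at an unadjusted p under 0.05). The SE in total RNA was larger than in RPF at many codons, such as AAA (0.163 against 0.087) and GTT (0.077 against 0.046). At some codons, such as TCT, it was smaller (0.055 against 0.073). A lack of calls in total RNA, or after division by it, may in part reflect this noise. Divided by the total RNA library of the same number, 0 RPF codons were called with limma (10 unadjusted), and 8 were called 1 codon toward positive offsets, where TCC rose by 0.25 (adjusted p = 0.0407). At 1 codon toward negative offsets 31 were called, 14 higher and 17 lower. Next to the codon, the count was 11 without RPF plus replicate 1, 13 without minus replicate 1 and 10 without minus replicate 2. The AGT call was lost without each of these 3 (adjusted p 0.0907, 0.0723 and 0.068).

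**Figure D2:**
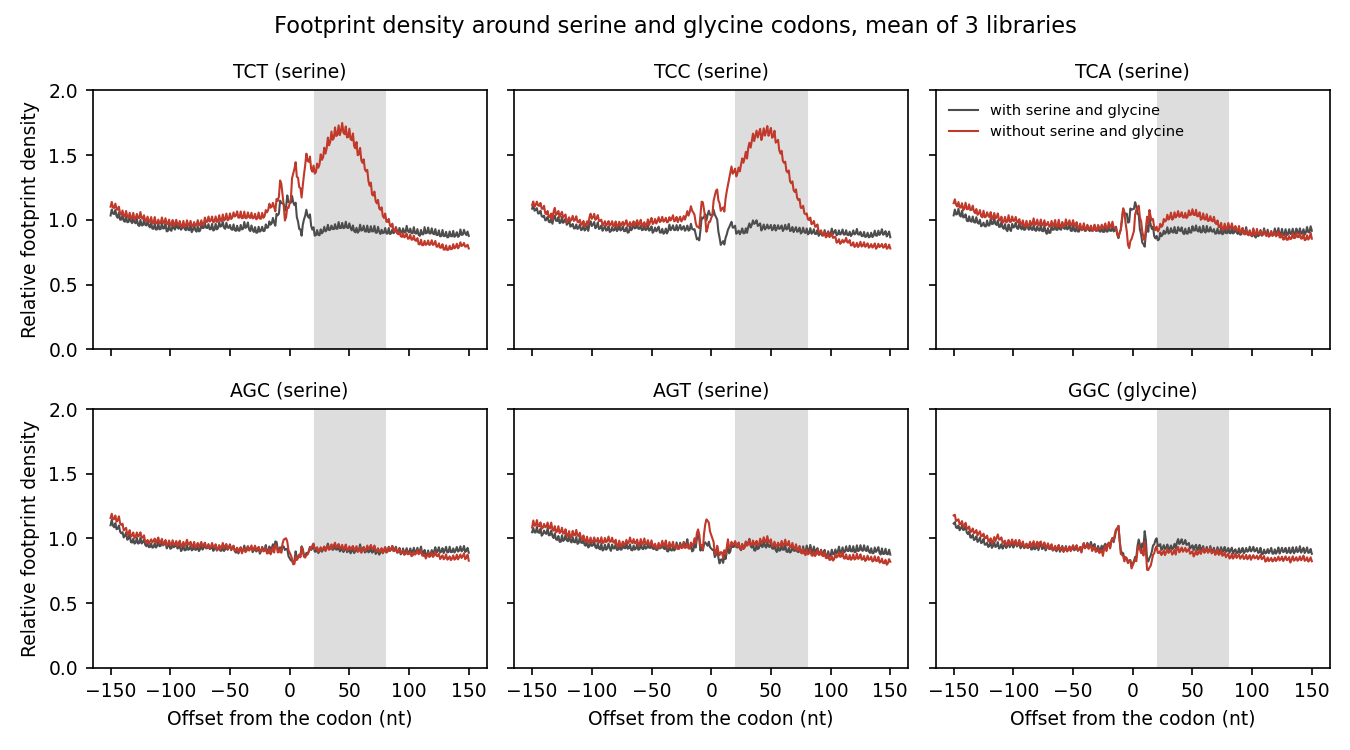
Relative footprint density (y axis, mean of 3 libraries) at each offset in nt from 5 serine codons and the glycine codon GGC (x axis), with serine and glycine in grey and without in red; the shaded band marks offsets 21 to 80. In that band the mean density at TCT is 0.927 with and 1.46 without the amino acids and at TCC 0.935 and 1.46, against 0.931 and 0.895 at GGC.

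Total RNA was compared to ask which mRNAs changed in amount. Of 8481 genes tested, 697 changed without serine and glycine, 389 upward and 308 downward. Genes of the unfolded protein response, which builds up the folding capacity of the endoplasmic reticulum, fell together. Of 19 members 12 fell (13 adjusted over the list alone), with a median log2 change of -1.31 (camera adjusted p = 4.79e-25, and adjusted p = 0.0447 with an estimated correlation). The chaperones CALR (chromosome 19, 12938609 to 12944489) and HSPA5 (chromosome 9, 125234853 to 125241343) fell 3.85-fold (log2 change -1.94, SE 0.11, n = 3 per group, adjusted p = 2.55e-08) and 3.13-fold (-1.65, SE 0.13, adjusted p = 6.52e-07). SDF2L1, a further member, fell from 141 ± 19.2 to 10.9 ± 4.18 CPM (SD, n = 3 each; adjusted p = 1.82e-05).

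Among the largest rises in total RNA were VGF, a neuropeptide precursor (0.968 ± 0.931 to 42.8 ± 12.1 CPM, SD, n = 3 each; adjusted p = 0.00162), MMP1, a collagenase (log2 change 5.32, SE 1.05; adjusted p = 0.00482), and SLPI, a secreted protease inhibitor (2.72 ± 3.23 to 53.6 ± 22.7 CPM; adjusted p = 0.00502). With serine and glycine VGF had 1, 0 and 1 counts and MMP1 2, 0 and 0, under the floor of 3 over a group, so the size of both rises is uncertain. ZNF717 and IL6R, the interleukin 6 receptor, had 0 counts in all total RNA libraries with serine and glycine. In total RNA they were at least 11.1-fold and 10.8-fold higher without, against a floor of 3 counts over the group. In RPF, ZNF717 had 2, 9 and 25 counts with and 7, 6 and 38 without the amino acids, so the groups overlapped. TRIM22, ZNF425 and WDR47 completed the 8 largest rises, with log2 changes of 5.13, 4.31 and 4.10 (SE 1.34, 0.93 and 1.21). TRIM22 had 0, 1 and 0 total RNA counts with serine and glycine, under the floor, so the size of its rise is uncertain. Its footprints had a log2 change of 0.67 (SE 0.43, edgeR adjusted p = 0.238). Besides SDF2L1 (-3.68, SE 0.40), the 8 largest falls were PMM1 (-4.57, SE 1.11), SLC17A5 (-3.91, SE 0.92), SGK3 (-3.52, SE 0.81), FAM114A1 (-3.01, SE 0.60), FGD3 (-3.01, SE 0.79), ALDH7A1 (-2.98, SE 0.82) and SOX12 (-2.97, SE 0.84). SGK3 shares its values with a readthrough transcript and is uncertain. VGF, SLPI, SDF2L1 and FAM114A1 were called whichever library was left out. The MMP1 call was lost without minus replicate 1 (adjusted p = 0.0594), SGK3 without minus replicate 2 (0.0548), ZNF425 without minus replicate 2 or 3 (0.0622 and 0.0708), and SLC17A5 without plus replicate 1 or minus replicate 1 (0.0802 and 0.0502). PMM1 lost it without plus replicate 1 or 2 or minus replicate 1 or 3 (0.0507 to 0.176), FGD3 without plus replicate 1 or 2 or minus replicate 2 or 3 (0.0638 to 0.0993), ALDH7A1 without any library but plus replicate 3 and WDR47 without any but plus replicate 1 (0.0639 to 0.234). ZNF717, IL6R, TRIM22 and SOX12 lost it without any 1 of the 6 (0.0546 to 0.23).

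Of 22 glycolysis and hypoxia genes 9 fell (10 lower and 2 higher adjusted over the list alone), among them GAPDH (-0.87, SE 0.05, n = 3 per group, adjusted p = 1.43e-08) and LDHA, which makes lactate (-1.30, SE 0.12, adjusted p = 5.42e-06); the list's adjusted p was 1.01e-06 and adjusted p = 0.052 with an estimated correlation. Of 25 DNA replication genes 4 fell (6 adjusted over the list alone), among them the licensing factor CDT1 (-2.22, SE 0.21, adjusted p = 5.6e-06), with adjusted p = 0.000494 for the list and adjusted p = 0.0558 with an estimated correlation. Of 18 nucleotide synthesis genes 3 fell (3 adjusted over the list alone), including GMPS and IMPDH2 of guanine nucleotide synthesis (-1.19 and -0.87), with adjusted p = 0.0354 and adjusted p = 0.185 with an estimated correlation. The nucleotide list lost its call without plus replicate 1 or minus replicate 3 (adjusted p 0.101 and 0.0813). Of 10 inflammatory cytokine and NF-kB genes 2 rose (5 adjusted over the list alone), TNFAIP3 (2.02, SE 0.27) and IL1A (1.25, SE 0.14), with a list adjusted p of 9.27e-06 and adjusted p = 0.052 with an estimated correlation. Of 15 histone genes, near-identical copies and so uncertain, 6 rose (8 adjusted over the list alone), with adjusted p = 5.57e-05 and adjusted p = 0.052 with an estimated correlation. Of 78 ribosomal protein genes 9 fell (15 lower and 1 higher adjusted over the list alone), with a median of -0.18, adjusted p = 3.56e-05 and adjusted p = 0.248 with an estimated correlation.

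Genes of the amino acid response driven by the transcription factor ATF4 did not move as a list in total RNA (median 0.03, adjusted p = 0.259). Of 23, 3 rose (3 higher and 2 lower adjusted over the list alone), including PPP1R15A, a phosphatase subunit that restores translation after stress (1.53, SE 0.15, n = 3 per group, adjusted p = 7.28e-06), and CEBPB (1.08, SE 0.23, adjusted p = 0.00701). ATF4 itself (chromosome 22, 39520559 to 39522686) had a change of 0.20 (SE 0.15, adjusted p = 0.481) and ASNS, asparagine synthetase, of 0.40 (SE 0.18, adjusted p = 0.204). SARS, the enzyme that charges serine tRNAs, rose by 0.73 (SE 0.18, adjusted p = 0.0192), a call lost without plus replicate 1, minus replicate 1 or minus replicate 2 (adjusted p 0.088, 0.0855 and 0.0506); GARS, its glycine counterpart, had a change of 0.21 (SE 0.15, adjusted p = 0.453). SHMT1 and SHMT2, which interconvert serine and glycine, had changes of -1.55 (SE 0.61, adjusted p = 0.136) and -0.08 (SE 0.19, adjusted p = 0.859), and SHMT1 passed with DESeq2 (adjusted p = 0.0447). The other lists with a camera test did not pass at the threshold. Genes marking acinar, endocrine, fibroblast or mesenchymal cells were not among those tested, and ductal genes went both ways, with SOX9 and KRT7 higher (1.71 and 0.41) and KRT19 and MUC1 lower (-1.13 and -2.24).

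The total RNA count was 462, 429, 423, 380 and 364 without plus replicate 1, plus replicate 2, minus replicate 1, minus replicate 2 and minus replicate 3, 1311 with DESeq2 and 1505 in the fit over all 12 libraries. Plus replicate 3 and minus replicate 1 had the lowest mean correlations within their own group (0.761 and 0.825), and 599 genes were called without both. The other plus libraries were at 0.804 and 0.781 and the other minus libraries at 0.866 and 0.868.

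Footprints were compared to ask which mRNAs held more or fewer footprints relative to the others in a library. Absolute amounts and the speed of ribosomes were not measured, so a rise in footprints is not by itself a rise in translation. Of 10212 genes tested, 3594 changed, 1879 upward and 1715 downward. Footprints on ribosomal protein mRNAs rose on 76 of 78 genes (78 adjusted over the list alone), with a median log2 change of 1.75 (camera adjusted p = 0.00465 with an estimated correlation). RPS20 (chromosome 8, 56067254 to 56074506) rose by 2.74 (SE 0.09, adjusted p = 1.8e-16) and RPL37A from 366 ± 40.8 to 2290 ± 45.4 CPM (SD, n = 3 each; adjusted p = 9.57e-17). Of 29 translation factor genes 23 rose and 2 fell (23 and 2 adjusted over the list alone; adjusted p = 0.0469 with an estimated correlation). The elongation factor EEF1A1 (chromosome 6, 73515750 to 73521032) rose from 4280 ± 69.8 to 20000 ± 742 CPM, and the initiation factor EIF5 fell by 1.87 (SE 0.13; adjusted p = 4.18e-20 and 5.17e-11).

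Footprints on unfolded protein response genes fell for 18 of 19 members (18 adjusted over the list alone), with a median of -1.49 (camera adjusted p = 0.00624 with an estimated correlation). CALR fell by 2.40 (SE 0.08) and HSPA5 from 5430 ± 478 to 1380 ± 58.3 CPM (SD, n = 3 each; adjusted p = 8.24e-17 and 4.07e-16). Of 29 DNA replication genes 20 fell (22 adjusted over the list alone; adjusted p = 0.032 with an estimated correlation), such as the helicase subunit MCM4 (-1.11, SE 0.10) and TYMS, which makes thymidylate (-1.48, SE 0.18). Of 17 inflammatory cytokine and NF-kB genes 10 rose (12 adjusted over the list alone; adjusted p = 0.0369 with an estimated correlation), among them TNFAIP3 (chromosome 6, 137866349 to 137883312; 34.0 ± 3.21 to 302 ± 15.5 CPM) and IL1A (714 ± 27.8 to 1550 ± 43.3 CPM). Of 24 glycolysis and hypoxia genes 14 fell and 2 rose (14 and 2 adjusted over the list alone), with a list adjusted p of 2.33e-06 and adjusted p = 0.273 with an estimated correlation. LDHA and the pyruvate kinase PKM fell (-1.38 and -1.35), whereas GAPDH and the growth factor VEGFA rose (0.66 and 1.04). CD68, the only immune or blood marker tested, rose by 1.37 (SE 0.27, adjusted p = 0.000262). Histone genes, uncertain as above, rose for 11 and fell for 3 of 15 (11 and 3 adjusted over the list alone), with adjusted p = 5.47e-08 and adjusted p = 0.166 with an estimated correlation. Of 15 p53 target genes 6 rose and 2 fell (7 and 2 adjusted over the list alone), with GADD45A (2.23, SE 0.14) and the cell cycle inhibitor CDKN1A (2.17, SE 0.25) higher, adjusted p = 0.0264 for the list and adjusted p = 0.166 with an estimated correlation. The p53 list lost its call without RPF plus replicate 3 or minus replicate 1 (adjusted p 0.0706 and 0.0579). Of 12 ductal and epithelial genes 7 fell and 3 rose (7 and 3 adjusted over the list alone), among them KRT19 (-1.16) and S100P (-1.30) lower and SOX9 (0.91) higher, with adjusted p = 0.023 and adjusted p = 0.547 with an estimated correlation.

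ATF4 footprints rose from 344 ± 17.1 to 872 ± 32.4 CPM (SD, n = 3 each; log2 change 1.34, SE 0.09, adjusted p = 2.57e-11), and those of PPP1R15A from 142 ± 19.2 to 687 ± 18.7 CPM (adjusted p = 5.06e-14). Of 25 genes of the ATF4 list 9 rose and 5 fell (10 and 5 adjusted over the list alone), and the list did not pass (median 0.09, adjusted p = 0.18). ASNS had a change of -0.07 (SE 0.09, adjusted p = 0.539). SARS rose by 0.87 (SE 0.10, adjusted p = 1.04e-07), and GARS had a change of 0.22 (SE 0.09, adjusted p = 0.0618). SHMT1 fell by 1.42 (SE 0.21, adjusted p = 1.12e-05), SHMT2 had a change of 0.28 (SE 0.13, adjusted p = 0.0833) and PSPH of 0.15 (SE 0.20, adjusted p = 0.585). Of 15 amino acid transporter genes 3 rose and 5 fell (3 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.442). The carrier SLC1A5 fell by 0.70 (SE 0.12) and the glycine carrier SLC6A9 by 1.71 (SE 0.38, adjusted p = 0.00111), whereas SLC38A1 rose by 0.40 (SE 0.10, adjusted p = 0.00323), a call lost with scaling by library totals (adjusted p = 0.209). The lists not given here did not pass. The largest single rises were MMP10, a stromelysin (0.332 ± 0.320 to 19.1 ± 5.57 CPM), MMP1 (3.44 ± 1.06 to 55.4 ± 15.2 CPM), SNAI2, a transcription factor of epithelial-mesenchymal transition (log2 change 3.99, SE 0.21), CATSPER1 and TMEM40 (log2 change 3.70 for both), NAV3 (3.62), CD163L1 (3.61) and SPHK1 (3.30). With serine and glycine CATSPER1 had 1, 16 and 2 RPF counts and TMEM40 2, 23 and 0, most of them in plus replicate 2. The size of both rises is therefore uncertain, at 3.18 to 5.47 and 3.04 to 6.32 over all settings tried. The largest falls were HAPLN1 (-3.91), SDF2L1 (-3.78), the keratin KRT4 (-3.74), ALPP (-3.54), ERO1B (-3.51), ZBED2 (-3.25), CRELD2 (-3.20) and FZD2 (-3.06).

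With scaling by library totals alone, the median of all genes in RPF shifted by -0.23 and 30.8% of 3946 calls were higher, against 52.3% with TMM. On that scale the ribosomal protein median was 1.52. The fit over all 12 libraries called 1882 genes.

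**Figure D3:**
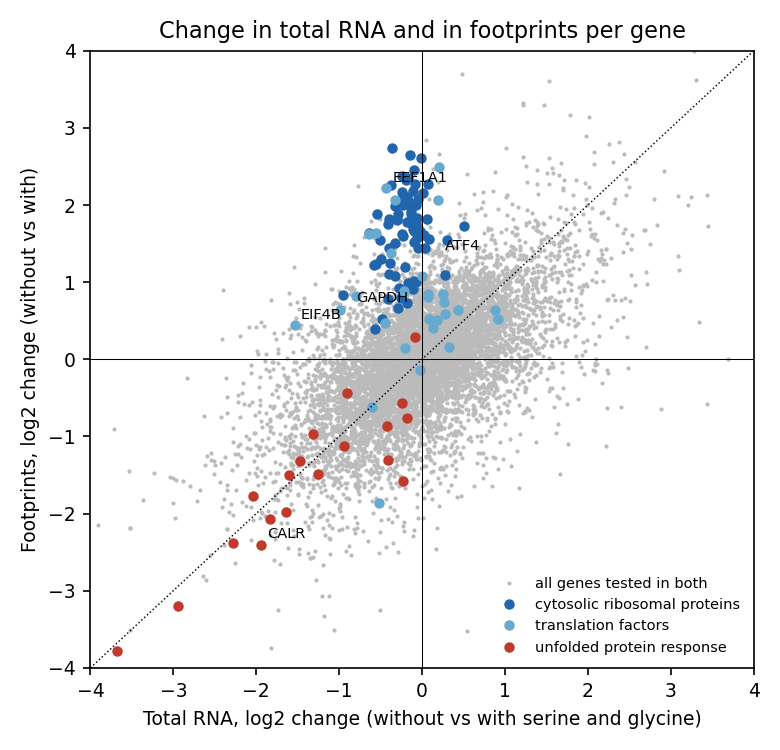
Log2 change in total RNA (x axis) and in footprints (y axis), without over with serine and glycine, for 8398 genes tested in both, of which 13 lie outside the axes; 3 gene lists are coloured and the dotted line marks equal change. Ribosomal protein genes lie near a median of -0.18 in total RNA and 1.75 in footprints (1.52 with scaling by library totals), and unfolded protein response genes near -1.31 and -1.49.

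Translational efficiency was compared to ask where footprints changed beyond the mRNA. Of 10211 genes, 2.82% changed, with 62.2% of the calls upward and 109 genes lower. Ribosomal protein genes made up 76 of the rises (78 adjusted over the list alone), with a median log2 change of 1.82 (camera adjusted p = 1.57e-06 with an estimated correlation). Of 29 translation factor genes 15 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 0.000802 with an estimated correlation). RPS20 rose by 3.04 (SE 0.15, n = 3 libraries of each kind per medium, adjusted p = 2.13e-13), RPL37A by 2.74 (SE 0.15), EEF1A1 by 2.59 (SE 0.11, adjusted p = 4.94e-14), RPS3A by 2.57 (SE 0.19), RPS27 by 2.57 (SE 0.20), RPL12 by 2.56 (SE 0.17) and EEF1G by 2.33 (SE 0.11). The ferritin chains FTH1 and FTL rose by 1.92 (SE 0.10) and 1.56 (SE 0.25). GAPDH rose by 1.47 (SE 0.08, adjusted p = 7.55e-13) and IMPDH2 by 1.24 (SE 0.19). ATF4 rose by 1.09 (SE 0.17, adjusted p = 0.000148).

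The remaining large rises in translational efficiency were PMM1 (4.70, SE 1.24, adjusted p = 0.0345) and EIF4E2, a cap-binding protein (2.68, SE 0.62, adjusted p = 0.0122). The PMM1 value rests on a fall in total RNA, from 21, 44 and 7 counts with serine and glycine to 0, 2 and 1 without. Its RPF counts overlapped, at 29, 43 and 47 with and 47, 23 and 20 without. The largest falls were B4GALT2 (-4.86, SE 0.93), C19orf48 (-4.63, SE 1.04), SORD (-3.57, SE 0.94), TAF1C (-2.90, SE 0.80), CRY1 (-2.53, SE 0.69), CGGBP1 (-2.37, SE 0.52), HERPUD2 (-2.30, SE 0.58) and UBQLN2 (-2.22, SE 0.45). Several of these values rest in part on a rise in total RNA. UBQLN2 went from 19, 14 and 11 total RNA counts with serine and glycine to 61, 57 and 39 without. CGGBP1 went from 25, 17 and 7 to 67, 40 and 74, SORD from 2, 4 and 0 to 11, 11 and 10, and TAF1C from 25, 22 and 1 to 93, 41 and 29. Total RNA counts of B4GALT2 and C19orf48 overlapped between the media. C19orf48 had 0, 1 and 0 RPF counts without serine and glycine, under the floor of 3 over a group, so the size of its fall is uncertain. The tRNA synthetase AARS fell by 0.81 (SE 0.15, adjusted p = 0.000721). AARS total RNA rose by 0.68 to 0.91 over all settings tried, so this value rests in part on a rise in mRNA. ASNS had a change of -0.54 (SE 0.18, adjusted p = 0.134), SARS of 0.09 (SE 0.20, adjusted p = 0.923), GARS of -0.05 (SE 0.18, adjusted p = 0.965), SHMT1 of 0.05 (SE 0.60, adjusted p = 0.993), SHMT2 of 0.31 (SE 0.24, adjusted p = 0.672) and PSPH of 0.15 (SE 0.41, adjusted p = 0.94). No list other than ribosomal proteins and translation factors passed, unfolded protein response genes included (median -0.29, adjusted p = 0.368). The ductal and epithelial list passed with scaling by library totals and without RPF plus replicate 3, with a camera adjusted p as low as 0.0112. B4GALT2, EIF4E2, CGGBP1 and UBQLN2 were called whichever library was left out. C19orf48 lost the call without RPF minus replicate 1 or 3 (adjusted p 0.0755 and 0.0542). PMM1 lost it in 9 of 12 such fits, SORD, TAF1C and CRY1 in 10 each and HERPUD2 in 8, with adjusted p of up to 0.129, 0.129, 0.312, 0.174 and 0.102.

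With limma on the log-ratio of same-numbered libraries, 0 genes passed, with 922 at an unadjusted p under 0.05, and DESeq2 called 433. The edgeR model over all 12 libraries used a common dispersion of 0.091, against 0.128 for total RNA alone and 0.052 for RPF alone. Its p-values may therefore understate the spread of total RNA and overstate that of RPF. With scaling by library totals the median of all genes shifted by -0.19 and 36.4% of 393 calls were higher, against 62.2% with TMM.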

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

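The tests in this part were chosen only after the result was seen, as was the region of offsets itself. Density at offsets 21 to 80 was not the measure of any planned comparison. In that region 3 serine codons showed a signal that exceeded the level with serine and glycine in every library. At offsets 21 to 80 relative to -80 to -21, density rose by 0.55 on the log2 scale at TCT, by 0.56 at TCC and by 0.10 at TCA (SE 0.01 each, n = 3 per group, limma adjusted p 1.68e-15, 2.41e-16 and 6.25e-06). The rise was largest at offset 44 for TCT (1.75 against 0.977) and 47 for TCC (1.73 against 0.964). AGC, AGT and TCG had changes of 0.00, -0.01 and -0.02, the glycine codons of -0.06 to -0.10, and 55 codons fell, so that the 6 serine codons ranked highest of 61.

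A slope along the coding sequence shared by all codons is argued against by the non-serine codons, whose median change was -0.091, and uneven coverage shared with total RNA by the change of 0.034 at TCC there (adjusted p = 0.998). A hypothesis is that ribosomes slowed where charged tRNA-Ser(AGA), which reads TCT and TCC, was scarce. The product of its read share and charged fraction was 0.00954% ± 0.00156 of reads without serine and glycine (SD, n = 3) against 0.272% ± 0.292 with them, and the lowest of the 4 cytosolic serine anticodons in all 3 libraries without them, with Ser(CGA) next at 0.115% ± 0.0194. It was also the lowest in 2 of 3 libraries with the amino acids, where density did not rise, its share may be set by reads exchanged with tRNA-Ser(TGA), and the charged fractions of both were alike, so the hypothesis stays open. At the 2 offsets next to the codon, the planned measure, TCT and TCC had changes of 0.02 and 0.00 (limma adjusted p 0.885 and 0.986). TCC rose by 0.25 when the measure was moved 1 codon toward positive offsets (limma adjusted p = 0.0407). Where ribosomes stood in relation to any of the offsets is also unknown, because the orientation of the offsets is not given in the sources used here.

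The 6 libraries of each kind can be divided in 10 ways, too few for a share under 0.05. In every division but the real one, each group holds libraries of both media. A change with medium then widens the spread within groups and favours few calls, so the counts of the other divisions do not measure chance. For codons at offsets 21 to 80 the real division called 58 and the highest of the others 0, and at the offsets next to the codon 24 and 0. For genes it called 697 and 0 in total RNA, 3594 and 0 in RPF and 2.82% of genes and 0 in translational efficiency, and for tRNA 26 and 0 in charging and 2 and 0 in abundance, so 1 of 10 divisions reached the real count in each.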

How the results depend on the processing

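Scaling by library totals, TMM without ribosomal protein and translation factor genes, leaving out the 2 total RNA libraries with the lowest correlation within their group, the region at offsets 21 to 80, charging by anticodon, the larger pseudocount and the logit with a read minimum were chosen after seeing the data. In total RNA, DESeq2 called 1311 genes and the fit over all 12 libraries 1505, against 697, and leaving out 1 library gave 364 to 659. In RPF the fit over all 12 called 1882 and counts thinned to the shallowest RPF library 3494, against 3594, and leaving out 1 library gave 2833 to 3613. In translational efficiency DESeq2 called 433 and limma on log-ratios 0 (922 at an unadjusted p under 0.05), against 2.82% of genes, with 1.95 to 3.03% when 1 library was left out. No gene called in these comparisons was called in the opposite direction in any setting. At the offsets next to the codon, division by total RNA gave 0 (10 at an unadjusted p under 0.05, limma), against 24, with 10 to 29 when 1 library was left out. Moving 1 codon toward positive offsets gave 8 and 1 codon toward negative offsets 31. In total RNA codon density 0 were called with limma (2 unadjusted). At offsets 21 to 80 leaving out 1 library gave 57 to 58, against 58. Charging gave 19 to 25 isodecoders and 7 to 16 anticodons, against 26 and 9. Abundance gave 4 on the untransformed share, 1 among classes above 0.1% of reads and 5 with the larger pseudocount, against 2, and 0 to 6 when 1 library was left out, the 0 with limma at 12 and 18 unadjusted. Changes of direction in which the main or the other value passed the threshold were SLC3A2 in RPF with library totals (-0.031, adjusted p = 0.76), TCC 1 codon toward positive offsets (0.25) and AGT at offsets 21 to 80 over the outer flanks (0.0392). The cause was not tested, except that fewer libraries were fitted when 1 was left out.

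For the genes named in RPF 1382 values kept direction and side of the threshold, 66 no longer passed and 7 newly passed, for total RNA 857, 132 and 3, and for translational efficiency 802 did, 20.6% of values no longer passed and 2 newly passed. Same-numbered libraries did not pair for genes, and for tRNA this is open: correlations of deviations lay between -0.055 and 0.010 for genes, were -0.003, 0 and -0.185 for charging, 0.309, 0.094 and 0.277 for abundance and 0.018, 0.509 and -0.737 for codons, and 0 and 2 of 3 plus tRNA libraries were closest to their own number in charging and abundance. The share of spiked oligonucleotides fell with replicate number in both media (2.34, 1.07 and 0.844% with and 3.01, 1.28 and 0.771% without serine and glycine). With the replicate block 623 genes were called in total RNA, 3557 in RPF and 2.38% in translational efficiency, and 230 genes there with the block within each medium. For codons the replicate block gave 22 at the offsets next to the codon and 58 at offsets 21 to 80, and for tRNA 19 isodecoders, 8 anticodons and 2 abundance classes. Of simulated 1.5-fold changes 0% were recovered in translational efficiency and 3% in total RNA, against 23.9% in RPF. Limits of depth and of spread were not separated, as total RNA was both shallower and more dispersed (0.128 against 0.052). The alternatives on codon content of coding sequences were not run.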

Other observations

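The sums of tRNA shares, the correlation with coding length, the tests of scaling and of shared reads and the 3 gene lists that follow were chosen only after the result was seen. The comparison with matched genes was set before its result, and the gene and tRNA tests behind the patterns were planned. Interferon-stimulated genes were higher without serine and glycine in both total RNA and footprints. Of 35 such genes 19 rose and 0 fell in total RNA by edgeR, with a median log2 change of 1.10 (camera adjusted p = 0.000553 with an estimated correlation), and 30 rose and 0 fell in RPF, with a median of 0.94 (adjusted p = 0.00165). ISG15, a ubiquitin-like modifier, rose by 1.94 (SE 0.13) and 1.89 (SE 0.08) and the antiviral RSAD2 by 1.86 (SE 0.38) and 2.33 (SE 0.12) in total RNA and RPF (n = 3 per group). In translational efficiency 0 rose and 1 fell, PARP14 (-0.81, SE 0.18, adjusted p = 0.0118). Since the genes were picked after their values were seen, these p-values describe the list and are not independent evidence.

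Immediate early genes, which respond to growth factors and stress, rose for 8 of 15 in total RNA and 14 of 17 in RPF (0 fell in both by edgeR; adjusted p 0.00317 and 0.00883 with an estimated correlation), among them KLF6 (2.07, SE 0.23, and 2.53, SE 0.11). Genes of matrix remodelling and migration rose for 9 of 13 and 11 of 15 (0 fell in both; adjusted p 0.00158 and 0.0106 with an estimated correlation), with LAMB3, a laminin chain, at 1.89 (SE 0.12) and 1.34 (SE 0.09), and SNAI2 at 3.28 (SE 0.41) and 3.99 (SE 0.21). In translational efficiency 0 of 18 immediate early genes were called with edgeR. Of 14 matrix genes 0 rose and 2 fell there, LAMB3 (-0.60, SE 0.16, adjusted p = 0.0313) and ITGA3 (-1.06, SE 0.17, adjusted p = 0.00013). ITGA3 rose in total RNA (0.98) but not in RPF (-0.02).

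Footprints rose on 76 of 78 ribosomal protein and 23 of 29 translation factor mRNAs, with EIF5 among the factors lower. In total RNA 2 of the factors rose and 7 fell, while 9 ribosomal proteins fell and 0 rose. EIF4B was among the factors with lower total RNA, with log2 changes of -1.6 to -1.47 over all settings tried. For such genes the lower mRNA is part of the rise in translational efficiency. Short coding length or high expression as the whole cause is argued against by 314 other genes matched on both, whose median translational efficiency changed by 0.01 (quartiles -0.26 and 0.38), against 1.74 for the 107 listed genes, although the match was incomplete, with median lengths of 1032 and 567 nt and levels of 8.64 and 9.83 log2 CPM. Over all genes, shorter coding length went with a higher change in translational efficiency (Spearman correlation -0.153) and RPF (-0.162), so a part played by length stays open. The choice of TMM over library totals as the whole cause is argued against by the ribosomal protein median of 1.52 in RPF with library totals. Both scales are relative to the library, so neither can show whether the absolute number of footprints on these mRNAs rose. A rise in reads shared with pseudogenes that both kinds of library have in common is argued against by the total RNA median of -0.18. That median cannot show whether reads were shared to an equal extent in both media, and the treatment of reads with several matches is unknown. A change in the translation of these mRNAs may be a biological response to the medium, as a hypothesis found and tested on the same data.

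The share of tRNA-Pro(TGG) rose as that of Pro(CGG) went from 4.16% ± 0.459 to 1.03% ± 1.01 of reads (SD, n = 3 each; limma adjusted p = 0.0977), and Ser(TGA) and Ser(AGA) went in opposite directions. The call for Pro(TGG) was lost without plus replicate 2 or minus replicate 2 (adjusted p 0.0547 and 0.0889). Reads moving between near-identical tRNA sequences may account for part of this, because the sum of Pro(AGG), Pro(CGG) and Pro(TGG) changed by 0.50 on the log2 scale, against 2.57 for Pro(TGG), and the sum of Ser(AGA) and Ser(TGA) by 0.56, against -2.42 for Ser(AGA). A true change in tRNA amounts stays open and was not tested.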
